A study of Homo sapiens with 2 samples.

How the data were processed

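Single-cell RNA profiles were measured in 2 intracranial xenografts of D425, a human Group 3 medulloblastoma cell line with amplified MYC. Group 3 is 1 of the molecular subgroups of medulloblastoma, a malignant tumour of the cerebellum. Per the labels' protocols, D425 cells (WT) or D425 cells with a knockdown (KD) of the long noncoding RNA lnc-HLX-2-7 were injected into the cerebellum of NOD-SCID mice, an immunodeficient strain. The tumours were harvested after 30 days. Cell suspensions were loaded on a droplet instrument (10x Genomics Chromium) with a target of 8000 cells. This assay tags the 3' end of each captured RNA with a cell barcode and a unique molecular identifier (UMI). The sample labels call the change a KD and the series title a knock out. Each group had 1 sample.

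The deposited values were UMI counts per gene and barcode, and the authors joined both libraries in 1 matrix of 90017 features and 15589 barcodes. Per the file headers the matrix was written by Cell Ranger 3.1.0. Per the submitters' processing notes, STAR 2.7.0d, the build hg38, Seurat 3.1.2 and R 3.6.1 were also used, with no role given. The deposited list of barcodes (other values, text) carries a library number, and the deposited list of features (other values, text) carries gene names. No label ties a library number to a group, so the libraries were kept unassigned as library 1 and library 2, and no direction between WT and KD was drawn. Whether the deeper library was thinned when the libraries were joined is not stated.

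The features held 60669 human Ensembl IDs, 29305 names that start with lnc- from a catalogue of long noncoding RNAs, 43 other names and 0 mouse IDs. Of the Ensembl IDs, 96.4% were found in GENCODE 29, which gave the coordinates (GRCh38). The lnc- features had no coordinates and some may share transcripts with Ensembl genes or with each other. With no mouse features, the species calls and the host cell types of the design could not be run.

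Choices made before the data were examined were the filters, the gene lists, the comparisons, the thresholds, the rule for named genes and most of the other settings tried. A barcode passed with at least 500 genes and a mitochondrial share of at most 20%, and with no doublet call. Doublets were called with the Scrublet method in Scanpy 1.11.5. Its first run, over barcodes below the gene minimum as well, called most of library 2, so the call was repeated on filtered barcodes alone. That repeat called 8 barcodes of library 1 and 15 of library 2, a share of 0.144% and 0.499%, so doublets were in practice not removed.

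UMIs were summed over the passing barcodes of each library and given as CPM, UMIs scaled to the same total in each library, of its 35227623 (library 1) or 49590342 (library 2) UMIs. With no replicates there was no test and no replicate check. Intervals are 95% and cover counting error only. They are exact Poisson for a CPM, exact conditional binomial for a ratio and Clopper-Pearson for a share. A count of 0 was given the limit of 3 UMIs. Genes were called apart at a ratio of at least 2 with at least 50 CPM in either library.

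Named genes were, by the fixed rule, the 12 highest and the 12 lowest ratios at 50 CPM or more without mitochondrial and ribosomal protein genes, a fixed set (HLX, MYC, OTX2, NRL, CRX, MKI67, TOP2A and MALAT1), every gene with HLX in its symbol, the 4 leading members of each list that stood apart, the genes of the subgroup panels and the 5 leading genes of each cluster. Genes chosen after their values were seen are named as such.

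Gene lists fixed beforehand were scored by the median log2 ratio of library 2 over library 1 among members with at least 10 CPM in the mean of the libraries. A list with 3 or more such members stood apart when its median lay outside the central 95% of 10000 random lists of the same size and matched expression. Members were counted as higher or lower at a ratio of 1.5. For the cell cycle, barcodes were thinned to 1500 UMIs. Clusters were made with Scanpy and python-igraph 0.11.9 (Leiden) from 2000 variable genes, 30 principal components and 15 neighbours at a resolution of 0.6.

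Chosen after seeing the data were the groups of library 2 barcodes under 700 UMIs, with at least 3000 UMIs and with at least 5000 UMIs, the clustering of library 2 alone, the dispersion and the chromosome arms. The dispersion of a gene is its variance between barcodes over the variance of draws from the library's summed profile at the same UMI totals, so that 1 means barcodes that differ by counting alone. It was computed on the 300 most abundant genes. Arm medians used genes with at least 20 CPM, on arms with at least 30 such genes, and approximate centromere positions. To correct a ratio for its arm, the arm median was subtracted and the median of all genes on arms, 0.07, added back.

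Other settings tried were other gene and mitochondrial filters, doublet calls kept, median-ratio scaling, the trimmed mean of M values (TMM, edgeR 4.0.16), barcodes weighted equally, thinning, other expression floors, other thinning levels, Leiden resolutions 0.3 and 1.0, and clustering without cell cycle genes. Scaling subtracted 0.10 (median-ratio) and -0.09 (TMM) from every log2 ratio, so ratios fell with the first and rose with the second. The steps were tested on simulated data in which 99% of 3-fold genes and 0% of 1.5-fold genes were called apart. In that simulation, lists of unchanged genes fell outside the central 95% in 3.5% of cases, and barcodes drawn from 1 profile had a dispersion of 0.999. Leiden split such draws into 2 clusters. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, matplotlib 3.10.9 and R 4.3.3 were used.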

Results

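The data were droplet single-cell RNA counts of 2 human tumour xenografts grown in mouse cerebellum, 1 from unmodified D425 cells and 1 from D425 cells with lnc-HLX-2-7 knocked down. Group 3 medulloblastomas are marked by high MYC and by genes of the photoreceptor programme. The libraries are called 1 and 2 because no label ties a number to a tumour, and there were no replicates. Library 1 held 35344279 UMIs in 5547 barcodes, with a median of 5055 UMIs and 1933 genes. Library 2 held 56615025 UMIs in 10042 barcodes, with a median of 634.5 UMIs and 392 genes. In library 2, 5625 barcodes (56.0%) had under 700 UMIs, while 2119 had 5000 or more. The filters kept 5539 barcodes of library 1 (99.9%, interval 99.7 to 99.9) and 2993 of library 2 (29.8%, interval 28.9 to 30.7). The kept barcodes had medians of 5044 and 11539 UMIs.

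Library 1 barcodes differed from each other by counting error alone, while library 2 barcodes differed in cell cycle, ribosomal, photoreceptor and MYC target genes. Over the 300 most abundant genes the median dispersion was 1.00 in library 1 (5th to 95th percentile 0.966 to 1.03) and 4.50 in the 1859 passing library 2 barcodes with at least 5000 UMIs. For the summed genes of the G2/M list, which act at mitosis, it was 1.00 and 54.5. TOP2A, a topoisomerase, and CENPF, a kinetochore protein, peak together before mitosis. Their correlation over barcodes was -0.0088 in library 1 and 0.642 in those library 2 barcodes (CENPF was chosen after its values were seen). In library 2 both measures depended on depth, and those library 2 barcodes were deep, with a median of 24937 UMIs. Thinned to 1500 UMIs, they had a correlation of 0.416 and a G2/M dispersion of 4.91. Library 1 thinned alike had -0.0053 and 1.02. The SD of the mitochondrial share was 0.352 percentage points over the kept barcodes of library 1 and 2.09 over those library 2 barcodes. Values of library 1 are therefore given below as 1 profile rather than as values of cells.

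**Figure D1:**
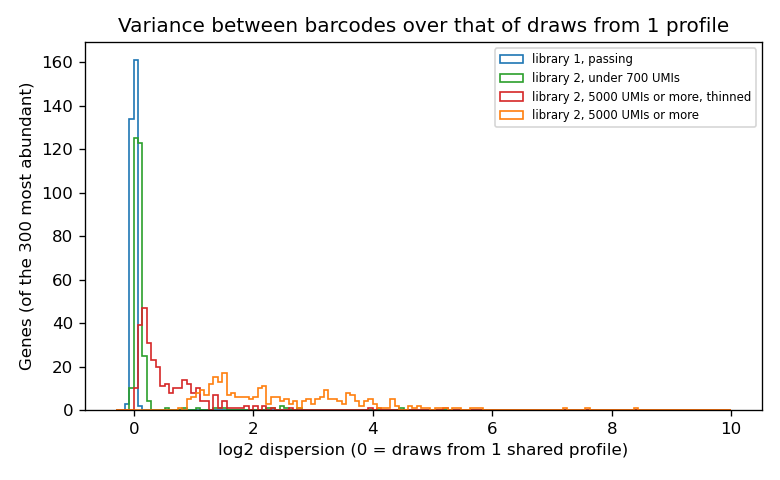
Histogram of the log2 dispersion of the 300 most abundant genes (vertical axis, number of genes) in library 1, in library 2 barcodes under 700 UMIs and in those with 5000 UMIs or more, as measured and thinned to 1500 UMIs. Library 1 sits at 0, with a median dispersion of 1.00, against 4.50 for library 2 barcodes with 5000 UMIs or more and 1.29 for the same barcodes thinned.

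The first comparison asked whether the targeted locus differed between the tumours. HLX, a homeobox gene beside the targeted RNA, measured 21.7 CPM (20.2 to 23.3) in library 1 and 12.6 CPM (11.6 to 13.6) in library 2, a log2 ratio of library 2 over library 1 of -0.79 (-0.95 to -0.64). HLX (ENSG00000136630.13) lies on chromosome 1 from 220879400 to 220885059 in GRCh38. Its antisense RNA HLX-AS1 measured 1.33 CPM from 47 UMIs and 0.766 CPM from 38 UMIs. The feature lnc-HLX-3 measured 5.31 and 1.61 CPM, a log2 ratio of -1.72 (-2.11 to -1.33). No feature carries the name lnc-HLX-2-7, so the targeted RNA has no value. The feature lnc-HLX-2, closest to it by name but not matched to it by coordinates, had 0 UMIs in both libraries, as did lnc-HLX-4 and lnc-HLX-6, which allows up to 0.0852 CPM in library 1 and 0.0605 CPM in library 2. The neighbouring genes MARK1, a microtubule kinase, TAF1A, a factor of RNA polymerase I, and RAB3GAP2, a regulator of RAB3, were also at lower CPM in library 2. They measured 14.6 against 11.8, 14.5 against 10.1 and 25.3 against 17.9 CPM. Of the genes below the floor of the list, C1orf115 measured 9.85 against 5.53 CPM, while DUSP10, a phosphatase, at 8.60 against 8.63 CPM and MTARC2 at 2.55 against 2.98 CPM were not lower. The 4 measured genes of the locus had a median log2 ratio of -0.51, at percentile 2.05 of random lists, and -0.20 after thinning, within them. The long arm of chromosome 1 as a whole had a median of -0.34, against 0.07 for all genes on arms. Corrected for that difference HLX was at -0.38 and the locus list at -0.10, within its random lists (percentile 35.2).

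The second comparison asked which genes differed between the tumours. MAGEA1, NPW and IMPG1 led the higher ratios in library 2, while 2 lnc- features, MT2A, PCAT1 and STMN2 led the lower ones. MAGEA1, a cancer-testis antigen (ENSG00000198681.7, chromosome X, 153179285 to 153183880), measured 18.8 CPM in library 1 and 107 CPM in library 2, a log2 ratio of 2.52 (2.40 to 2.64). NPW, a neuropeptide (ENSG00000183971.9, chromosome 16, 2009926 to 2020755), measured 25.9 and 148 CPM, with a ratio of 2.52 (2.42 to 2.62). IMPG1, a proteoglycan of the matrix around photoreceptors (ENSG00000112706.12, chromosome 6, 75921115 to 76072678), measured 13.7 and 51.1 CPM, with a ratio of 1.90 (1.76 to 2.04). PRCD, a photoreceptor disc protein, and AIPL1, a chaperone of the photoreceptor phosphodiesterase, had ratios of 1.51 and 1.47. The other high ratios were LINC00958 (1.61), the elastin cross-linking enzyme LOXL1 (1.44), the tubulin TUBA4A (1.33), the arginase ARG2 (1.30), the small GTPase RASD1 (1.23), the translational repressor NANOS1 (1.22) and the muscle troponin TNNC2 (1.22).

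At the other end, lnc-KCNE1B-3 measured 82.7 CPM in library 1 and 5.06 CPM in library 2, a log2 ratio of -4.03 (-4.22 to -3.84). The feature lnc-OR4F16-8 measured 168 and 16.8 CPM, with a ratio of -3.32. MT2A, a metal-binding metallothionein (ENSG00000125148.7, chromosome 16, 56608199 to 56609497), measured 53.9 and 10.2 CPM, with a ratio of -2.41 (-2.55 to -2.26). PCAT1, a noncoding RNA of the MYC region (ENSG00000253438.4, chromosome 8, 126556323 to 127419050), measured 136 and 45.5 CPM, with a ratio of -1.58. STMN2, a microtubule regulator of neurons (ENSG00000104435.14, chromosome 8, 79610814 to 79666175), measured 65.1 and 22.2 CPM, with a ratio of -1.55. The remaining ones were LINC02154 (-1.29), the filament protein SYNC (-1.26), AC015802.6 (-1.26), the giant muscle protein TTN (-1.16), LRTM1 (-1.11), lnc-SAMD11-13 (-1.11) and the retinoid receptor RXRG (-1.10). Among 2751 genes at 50 CPM or more, 20 were at least 2-fold higher and 17 at least 2-fold lower in library 2, together 1.34%, against 33 and 14 with TMM and 17 and 29 with median-ratio scaling. In library 2 barcodes under 700 UMIs, nearly all of which the filters left out, lnc-KCNE1B-3 stood at 103 CPM, lnc-OR4F16-8 at 147 CPM, SYNC at 112 CPM and AC015802.6 at 168 CPM, near or above their library 1 levels. With barcodes weighted equally, lnc-KCNE1B-3 and lnc-OR4F16-8 were at -1.90 and -1.90, STMN2 at -0.72, PCAT1 at -0.55, TTN at -0.55, AC015802.6 at -0.38 and SYNC at -0.35, most of them no longer 2-fold lower, and TNNC2 at 2.20.

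MYC, the amplified oncogene (ENSG00000136997.20, chromosome 8, 127735434 to 127741434), measured 594 CPM (586 to 602) in library 1 and 792 CPM (784 to 800) in library 2, a log2 ratio of 0.42. With library 2 barcodes under 700 UMIs in place of the kept ones it was -0.0434. OTX2, the homeobox driver of Group 3 tumours, measured 837 and 758 CPM, with a ratio of -0.14 that became 0.0017 when barcodes were weighted equally. The photoreceptor transcription factors NRL and CRX measured 21.97 against 27.6 CPM and 3.15 against 4.80 CPM. MALAT1, a noncoding RNA kept in the nucleus, measured 4638 and 5759 CPM, a ratio of 0.31 that became 0.90 with barcodes weighted equally and -0.36 with those under 700 UMIs.

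The third comparison asked which gene groups differed. Of 23 lists, 10 stood apart, where independent genes would give 1.15 by chance. Genes were not independent, since some lists share members and ratios moved together by chromosome arm (below). Photoreceptor genes had a median log2 ratio of 0.31 (18 members, percentile 99.6; 3 members were higher and 3 lower by 1.5-fold), and of -0.14 with library 2 barcodes under 700 UMIs in place of the kept ones. TULP1, a photoreceptor transport protein, measured 13.7 and 22.1 CPM, and RBP3, the retinoid carrier of the retina, 17.7 and 26.1 CPM. The lower members, chosen after their values were seen, were the phototransduction genes PDE6H (-0.86) and PDC (-0.79) and the photoreceptor protein RP1 (-0.59). MYC targets were at 0.23 (37 members, percentile 99.2; 2 higher and 0 lower), and within their random lists with barcodes weighted equally (0.17) or thinned (0.12), with library 2 barcodes under 700 UMIs (0.13) and corrected for their arms (0.15). Among them the transferrin receptor TFRC measured 66.1 and 114.9 CPM, the mitochondrial protein C1QBP 788 and 1182 CPM, the translation factor EIF5A 161 and 228 CPM, and the nucleolar protein RRP9 69.0 and 95.6 CPM. Cholesterol synthesis genes were at 0.26 (16 members, percentile 98.7), a call lost at a mitochondrial share of at most 10% (0.20), with barcodes weighted equally (0.29), after thinning (0.06), at 5000 UMIs or more in library 2 (0.23) and under 700 UMIs (-0.0083). The enzymes SC5D, IDI1 and DHCR7 measured 19.7 and 36.7, 60.7 and 97.9, and 8.91 and 13.2 CPM, and their regulator INSIG1 9.28 and 15.1 CPM. The glial list was at 0.58 on 3 members (percentile 99.1; 0.37 and within its random lists at a mitochondrial share of at most 10%), which were the chaperones CRYAB and CLU and the myelin enzyme CNP, at 16.4 and 24.8, 15.2 and 20.2, and 11.4 and 17.02 CPM.

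Genes encoded in the mitochondrial genome were lower in library 2, with a median of -0.69 and 11 of 13 members lower by 1.5-fold. The mitochondrial filter, which 533 barcodes with 500 genes or more exceeded in library 2 and 0 in library 1, enters this value, which was -0.38 with no limit and -0.87 with a limit of 10%. MT-ND6, the subunit encoded on the opposite strand, measured 1228 CPM in library 1 and 32.2 CPM in library 2, a ratio of -5.26. MT-ATP6 was at -1.11, MT-ND5 at -1.04 and MT-ATP8 at -0.97. S phase genes were at -0.16 (35 members, percentile 0.14), and within their random lists with library 2 barcodes under 700 UMIs (-0.14). Among them DTL, a ubiquitin ligase adaptor, was at -0.77, the histone chaperone CHAF1B at -0.61, the helicase HELLS at -0.57 and the chromatin factor ATAD2 at -0.55. ATAD2 was at -0.02 when corrected for its chromosome arm (below). G2/M genes were at -0.09 (46 members, percentile 0.67), and at 0.0171 with library 2 barcodes under 700 UMIs. The cytokinesis protein ANLN was at -0.86, RANGAP1 at -0.66, the nuclear envelope protein LBR at -0.61 and the histone chaperone ANP32E at -0.58. Histone genes were at -0.37 on 5 members (percentile 0.965), with the linker histones H1-2 at -0.47, H1-5 at -0.43 and H1-4 at -0.29 and H2AC6 at -0.37. The most abundant member, H4C3, was at 0.51, and the list was within its random lists with barcodes weighted equally (-0.11) and with library 2 barcodes under 700 UMIs (-0.0085). The nuclear-retained noncoding RNAs were at -0.52 on 3 members (percentile 1.89), with SNHG14 at -0.80, KCNQ1OT1 at -0.52 and MALAT1 at 0.31. Their median became 0.0783 after thinning to 1500 UMIs, and was within its random lists with barcodes weighted equally (-0.10) and with no mitochondrial limit (-0.40).

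Lists within their random range were TGF-beta and Activin targets (0.24), heat shock (0.21), neuronal differentiation (0.20, and -0.37 with library 2 barcodes under 700 UMIs), hypoxia and glycolysis (0.18), MAPK and JNK (0.16), the Group 3 panel (0.15), oxidative phosphorylation (0.10) and immediate early genes (0.10). Lists within their random range that stood apart under an alternative planned beforehand were immediate early genes with barcodes weighted equally (0.45) and thinned (0.55), neuronal differentiation (0.44) and MAPK and JNK (0.51) after thinning, and, with no floor on the CPM of members, TGF-beta and Activin targets (0.70), neuronal differentiation (0.39) and MAPK and JNK (0.34). With no such floor 15 lists stood apart in all, and not all of them are named here. Ribosomal proteins also stood apart after thinning, with their sign reversed. Hypoxia and glycolysis (0.19) and ribosomal proteins (0.0168) did so corrected for their arms. With library 2 barcodes under 700 UMIs, ribosomal proteins (0.22), extracellular matrix and migration (-0.44) and neuronal differentiation (-0.37) did. Both settings were chosen after seeing the data. Medians of ribosomal proteins (0.07), p53 and cell death (0.05), the unfolded protein response (0.01), stem and progenitor genes (-0.01) and extracellular matrix and migration (-0.07) changed sign under TMM or median-ratio scaling. The WNT, SHH and Group 4 panels and the interferon, MHC class I and dopamine lists had under 3 measured members.

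**Figure D2:**
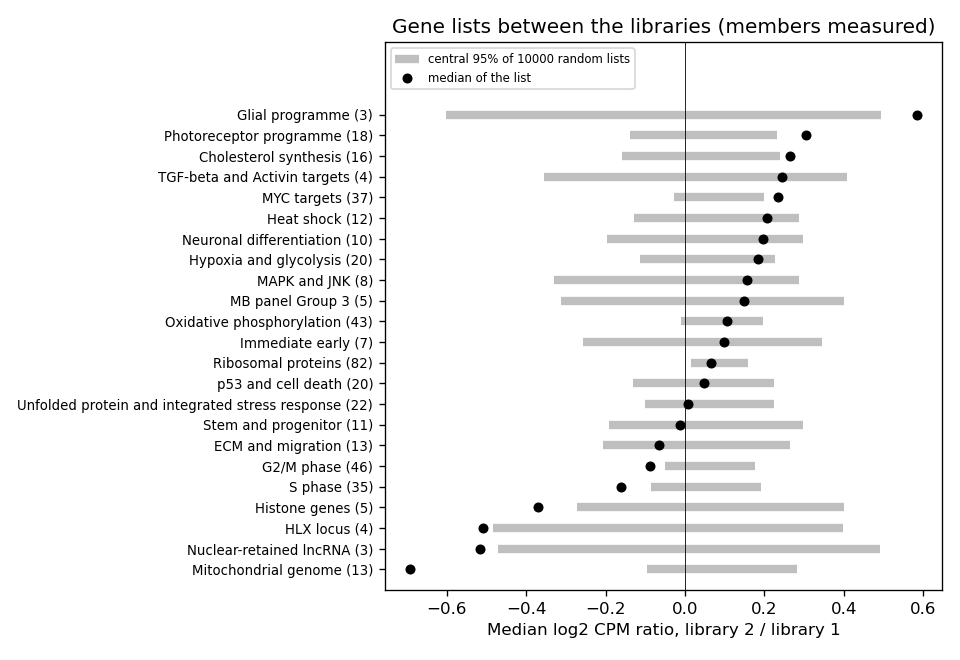
Median log2 CPM ratio of library 2 over library 1 (horizontal axis) for each list with 3 or more measured members, with the number of members in parentheses and the central 95% of 10000 random lists as a bar. Lists run from -0.69 for the mitochondrial genome to 0.58 for the glial list, and 10 of 23 lie outside their bar.

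Genes also moved by chromosome arm, a comparison chosen after the data were seen. Genes of 8q, the arm that carries MYC, had a median log2 ratio of -0.45 (157 genes), those of 16q -0.42 (82 genes) and those of 1q -0.34 (237 genes). Genes of 19q were at 0.50 (100 genes), of 18p at 0.48 (31 genes), of 17p at 0.36 (63 genes) and of 18q at 0.33 (69 genes). Below the median of all genes lay 94.3% of the genes of 8q, 97.6% of 16q and 95.4% of 1q. The SD of the medians of 41 arms was 0.203, and the highest of 1000 shuffles of genes over arms gave 0.0599. Corrected for the difference of the arm median from that of all genes on arms (0.07), MYC was at 0.94, PCAT1 at -1.05 and MT2A at -1.91. Of the cell cycle genes named above, ATAD2 was then at -0.02, ANP32E at -0.17, LBR at -0.20 and DTL at -0.36. RANGAP1 (-0.48), HELLS (-0.45), CHAF1B (-0.54) and ANLN (-0.64) changed less. With ratios corrected in this way, the MYC targets were at 0.15 (percentile 95.5) and no longer stood apart, while the photoreceptor (0.20), cholesterol (0.35), S phase (-0.07) and G2/M (-0.12) lists did. Hypoxia genes (0.19, percentile 98.0) and ribosomal proteins (0.02, percentile 1.78) then stood apart as well.

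**Figure D3:**
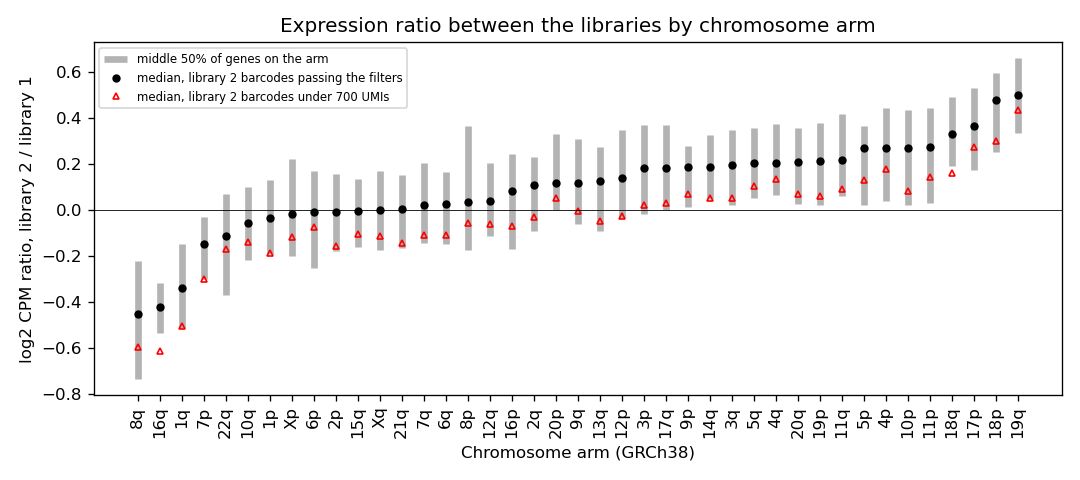
Median log2 CPM ratio of library 2 over library 1 (vertical axis) for the genes of each chromosome arm, with the middle 50% of genes as bars, and the same for library 2 barcodes under 700 UMIs as triangles. Arms run from -0.45 on 8q to 0.50 on 19q, and the arm medians of both barcode groups correlate at 0.985 across arms. Both are ratios over the same library 1 sum, so this correlation is in part built in.

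The next comparison asked how many barcodes carried RNA of proliferating cells. MKI67, a marker of cycling cells, measured 28.2 CPM in library 1 and 20.95 CPM in library 2, and TOP2A 156 and 139 CPM. At 1500 UMIs per barcode, 21.7% (20.6 to 22.8) of library 1 and 13.9% (12.4 to 15.4) of library 2 barcodes had a UMI of TOP2A. Barcodes drawn from the library's summed profile would give 21.5% and 17.97%. The share with MKI67 was 3.88% (3.39 to 4.42) and 2.52% (1.90 to 3.26), against 3.95% and 2.66% from a summed profile. Thinning left out 807 library 2 barcodes, and no cell type without these genes was at hand as a background for free RNA. The summed S phase list measured 1863 and 1660 CPM and the G2/M list 4268 and 3954 CPM.

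The kept barcodes of both libraries, with no call of species, formed 5 clusters when clustered together, each drawn almost wholly from 1 library. Clusters 1 (2929 barcodes) and 2 (2719 barcodes) were library 1 but for 24 and 94 barcodes and parted by depth, with medians of 8465 and 3105 UMIs. Both were led by MT-ND6, lnc-KCNE1B-3, lnc-OR4F16-8, MT2A and PCAT1. Cluster 3 (1709 barcodes, 57.1% of library 2) was led by NPW, MAGEA1, LINC00958, PRCD and AIPL1. Cluster 4 (959 barcodes, 31.8% of library 2) had a median of 1063 UMIs and was led by the globin HBB, LRRC75A, GOLGA8A, the thyroid hormone carrier TTR and MIPOL1. HBB and LRRC75A were also high in library 2 barcodes under 700 UMIs, at 172 and 313 CPM. At 5000 UMIs or more they were at 18.5 and 52.3 CPM. Whether cluster 4 holds cells was not tested. Cluster 5 held 216 barcodes, 7.22% (6.32 to 8.20) of library 2 and 0 of the 5539 of library 1. It was led by USP18, an interferon-induced protease, BTBD17, CDKN1C, an inhibitor of the cell cycle, MFAP4, a matrix protein, and SOHLH2, a germ cell transcription factor. Library 1 alone gave 2 clusters with medians of 3251.5 and 8929 UMIs, as did simulated draws from 1 profile.

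Library 2 was then clustered alone at 3000 UMIs or more, a choice made after seeing the data, and gave 8 clusters. Cluster 1 (367 barcodes, 18.7%) was cycling, led by the mitotic genes AURKB, UBE2C, CCNA2 and DLGAP5 and the histone H4C3, with TOP2A at 409 CPM against 49.2 CPM in the other clusters. Cluster 2 (359 barcodes) was led by the germline genes TEX101 and SOHLH1, LINC02087, NPW and the kinase MATK. Cluster 3 (293 barcodes) was led by LOXL1-AS1, the GTPase RAB31, AF279873.4, the adaptor STAP1 and LOXL1. Cluster 4 (256 barcodes) was led by TTR at 1260.4 CPM, the transporter SLC12A1, the protease CTSV, the cone phosphodiesterase subunit PDE6H and the dehydrogenase IDH1. Cluster 6 (208 barcodes) was led by LINC02154, the retinal bipolar and Purkinje cell gene PCP2, DIAPH2-AS1, the photoreceptor protein RP1 and the hypoxia gene BNIP3, and had TOP2A at 16.2 CPM. Cluster 7 (151 barcodes) had the highest median mitochondrial share, 13.9%, and was led by AC005261.5, lnc-MTUS2-1, lnc-CBY3-3, lnc-LOXL1-1 and lnc-EIF2B1-6. Cluster 8 (102 barcodes) was led by PAGE2B, MPC2, TTR, RPL6P27 and AP001324.1 with ratios under 2 and had ribosomal genes at 417049 CPM.

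Cluster 5 of library 2 (229 barcodes, 11.7%, interval 10.3 to 13.2) had low MYC and OTX2 and a high neuronal list, and held 194 of the 216 barcodes of the smallest joint cluster. MYC measured 186 CPM (171 to 203) against 830.1 CPM in the other clusters, and OTX2 185 CPM (169 to 202) against 787 CPM. The MYC target list was at -1.05, ribosomal proteins at -0.46, S phase genes at -0.58 and G2/M genes at -1.16. Higher were neuronal genes (2.57), the glial list (2.48 on 3 members), nuclear-retained RNAs (2.39 on 3 members), immediate early genes (2.05), matrix genes (1.26), p53 and cell death genes (0.70), photoreceptor genes (0.55) and the mitochondrial genome (0.26). In sum, however, the photoreceptor list was lower, at 4566 against 5157 CPM. The stem and progenitor list, at 0.46 and within its random lists (percentile 90.9), was higher in sum, at 4874 against 1924 CPM. NRL measured 106 against 23.0 CPM and CRX 37.5 against 2.701 CPM, but 71.4% of the NRL UMIs came from the 35 barcodes outside that joint cluster, where NRL was at 425.2 CPM and CRX at 109 CPM. In the 194 shared barcodes NRL was at 36.9 CPM and CRX at 21.96 CPM, while MYC was low in both parts, at 184 and 196 CPM. It was led by the muscle genes ACTC1 (231 against 0.329 CPM) and MYBPH, the adaptor SHD, the lipid droplet gene FITM1 and the Purkinje cell gene PPP1R17. Among genes chosen after their values were seen, the muscle transcription factors MYOD1 and MYOG measured 191 against 18.2 CPM and 103 against 1.32 CPM. STMN2 measured 179 against 12.01 CPM, MALAT1 23697 against 4526 CPM and TOP2A 36.5 against 144 CPM. Median depth was 9794 UMIs.

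Its barcodes split further into 4 subclusters, whose leading genes and list values are against the other barcodes of cluster 5. The largest (102 barcodes) was led by TTR, TTC12, PCP2, lnc-SOBP-1 and the cone transducin subunit GNGT2, and the photoreceptor list was at 1.65 and NRL at 161 CPM there. Summed, that list was at 6121 CPM there, against 5157 CPM in the other library 2 clusters. The next (61 barcodes) was led by CNTN2, an axonal adhesion molecule, PDZRN4, NEUROD2, a neuronal transcription factor, the interferon gene IFI44L and AC024940.2, with NRL at 94.6 CPM, the neuronal list at 2.12 and the photoreceptor list at -2.13. The third (43 barcodes) was led by SOHLH2, the receptor KISS1R, CEACAM16 and the muscle genes ACTC1 (1415 CPM) and MYL1, with NRL at 6.85 CPM. The smallest (23 barcodes) was led by H1-5, RRM2, UBE2C, MYBL2 and BIRC5, with the G2/M list at 2.13 and NRL at 5.78 CPM. Summed, the G2/M list was at 4845 CPM there, against 4031 CPM in the library 2 clusters other than 5 and 7261 CPM in cluster 1.

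**Figure D4:**
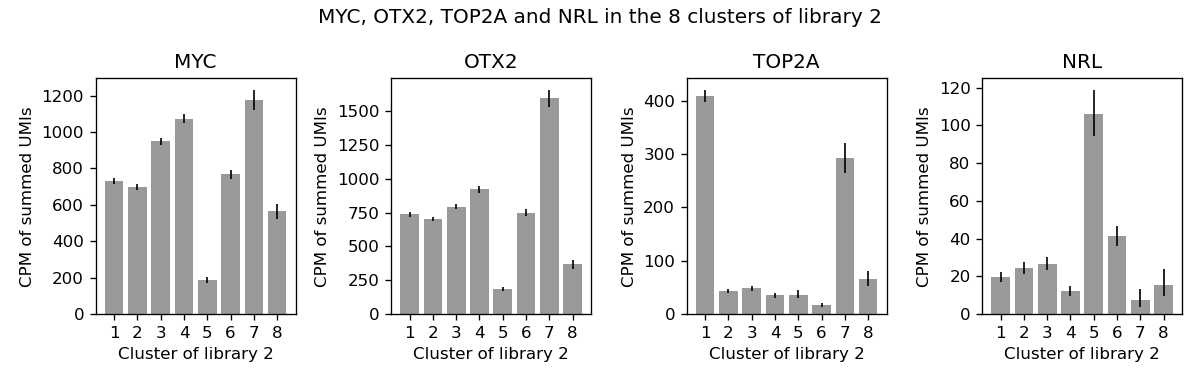
CPM of summed UMIs (vertical axes) of MYC, OTX2, TOP2A and NRL in the 8 clusters of library 2 barcodes with 3000 UMIs or more, with 95% Poisson intervals for counting error. Cluster 5 has MYC at 186 CPM and NRL at 106 CPM, 71.4% of it from 35 barcodes, and cluster 1 has TOP2A at 409 CPM.

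The last comparison placed the tumours among the subgroups of medulloblastoma. Group 3 panel genes were measured in both libraries. IMPG2, a photoreceptor matrix protein, was at 125 and 119 CPM, GABRA5, a GABA receptor subunit, at 29.3 and 15.3 CPM, and EYS, a photoreceptor protein, at 22.9 and 25.4 CPM. MAB21L2 and NPR3 had 3 UMIs or fewer in each library. Of the WNT panel, WIF1 and EMX2 had 0 UMIs, and TNC, GAD1 and DKK2 reached at most 2.12 CPM. Of the SHH panel, PDLIM3 was at 9.68 and 14.9 CPM, and EYA1, HHIP, ATOH1, SFRP1, GLI1 and GLI2 reached at most 1.19 CPM. Of the Group 4 panel, RBM24 was at 11.6 and 6.94 CPM, and KCNA1, EOMES, KHDRBS2, UNC5D, OAS1 and LMX1A reached at most 1.50 CPM.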

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

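Chosen only after the result was seen were the tests of TOP2A with CENPF and of library 2 in the same matrix, and the group of library 2 barcodes under 700 UMIs. Library 2 barcodes under 700 UMIs, which the filters left out almost wholly, appear above only beside the kept barcodes, and among genes at 50 CPM or more there, above the limit of 1.02 CPM that a count of 0 allows, the 6 with the highest ratio over library 2 barcodes with 5000 UMIs or more are given. LRRC75A measured 313 CPM (293 to 334) against 52.3 CPM, and 136 CPM in library 1. The globin HBB measured 172 CPM (157 to 187) against 18.5 CPM, and 0.0568 CPM in library 1. The feature lnc-OR4F16-8 measured 147 CPM against 14.6 CPM, and 168 CPM in library 1. The feature lnc-KCNE1B-3 measured 103 CPM against 3.70 CPM, and 82.7 CPM in library 1. The feature lnc-DDX18-9 measured 90.2 CPM against 2.07 CPM, and 0.994 CPM in library 1. MTRNR2L6, a copy of mitochondrial ribosomal RNA in the nuclear genome, measured 60.9 CPM against 1.75 CPM, and 0.738 CPM in library 1.

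Library 1 barcodes varied like draws from 1 profile in their most abundant genes, so cells of different phase or state were not seen there. Low depth is argued against, since library 2 barcodes thinned to 1500 UMIs still had a dispersion of 4.91 for the G2/M list. A uniform population of intact cells is argued against for the cell cycle genes. Library 1 held S phase genes at 1863 CPM and G2/M genes at 4268 CPM, against 1660 and 3954 CPM in library 2. Thinned to 1500 UMIs, their dispersion was 0.992 and 1.02 in library 1. In library 2 barcodes with 5000 UMIs or more, thinned alike, it was 2.29 and 4.91. Uniform cells would each have to hold S phase and G2/M RNA in the same shares. The correlation of TOP2A and CENPF in library 1 (-0.0088) follows from the pattern itself and cannot decide. An effect of joining the libraries stays open. The median dispersion of 4.50 in library 2 does not bear on an effect in library 1 alone. Free RNA of a common pool may be the source and stays open too. Its test compared log2 ratios over library 2 cells across 2748 genes, rather than the profiles themselves. Ratios of library 1 over a part of these cells were set against ratios of low-UMI barcodes over the remaining cells. They correlated at 0.246 (Spearman rho 0.127, genes not being independent replicates), between the bounds set for and against free RNA. Arm medians had an SD of 0.203 between the libraries and 0.0322 between library 2 cells and low-UMI barcodes, so arm shifts enter mainly the library 1 ratios. No difference between the groups was tested, because each had 1 library and the libraries carry no group.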

How the results depend on the processing

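The alternatives with library 2 barcodes of 5000 UMIs or more, or under 700 UMIs, and with ratios corrected for their arm were chosen after seeing the data. Where values moved or reversed, the cause was not tested. The count of genes at least 2-fold higher in library 2 (20) became 33 with TMM, 32 after thinning, 47 at 20 CPM and 7 at 100 CPM, these last by the number of genes admitted. The count of lower genes (17) became 26 at a mitochondrial share of at most 10%, 29 with median-ratio scaling, 10 with barcodes weighted equally, 11 after thinning, 81 at 20 CPM, 8 at 100 CPM and 55 with barcodes under 700 UMIs. The log2 ratio of HLX (-0.79) was -1.09 with those barcodes and -0.38 corrected for its arm, and negative under every alternative run. With barcodes under 700 UMIs, MYC (-0.0434), MALAT1 (-0.36), lnc-KCNE1B-3 (0.32), SYNC (0.0030) and AC015802.6 (0.75) reversed, as did the photoreceptor (-0.14), neuronal (-0.37), G2/M (0.0171) and cholesterol (-0.0083) lists. OTX2 reversed to 0.0017 with barcodes weighted equally, and after thinning so did ribosomal proteins (-0.0386) and nuclear-retained RNAs (0.0783). The share of barcodes with TOP2A (21.7% and 13.9%) followed depth by construction, at 57.1% and 39.6% unthinned and 11.3% and 8.68% at 750 UMIs. Library 2 kept 8930 barcodes at a minimum of 200 genes. Joint clusters numbered 3 at resolution 0.3 and 8 at 1.0, and the smallest one's cells then fell in clusters with 58.9% and 10.4% of library 2. Counts, HLX, shares and clusters stayed within their limits in 52 planned and 10 added cases and moved beyond them in 19 and 3. The limit was a change of 1.5-fold for counts of genes, lists, barcodes and clusters, so 15 lists in place of 10 lay within it. For HLX and shares it was the interval of the main value. Named genes, lists and the MKI67 shares stayed within theirs in 373 and 95, and moved beyond counting error with their sign kept in 94 and 40. With their sign kept, lists lost their call in 10 and 6 cases and gained one in 7 and 4. Not run were species shares of 75% and 99% and the host cell type alternatives, for lack of mouse features. Depth limits library 2, where 6501 barcodes had under 500 genes.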

Other observations

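Chosen only after the result was seen were the clustering of library 2 alone and its repeat without list genes, the comparison of arms between library 2 barcodes, and the tests of depth in doublets and of the MYC neighbours. Chromosome arms shifted together between the libraries. At least 94.3% of the genes of 8q, 16q and 1q lay below the median of all genes, so the shift of these arms was not that of a few genes. These arms had the lowest medians of 41, so a majority below was given by their choice. Transcript GC content and length are argued against, since they left 100.65% of the SD of the arm medians. Within library 2, arm medians of barcodes with 5000 UMIs or more over those under 700 UMIs had an SD of only 15.96% of that between the libraries. Low-UMI barcodes of library 2 therefore did not shift by arm in this way. That comparison holds no library 1 barcodes, so it cannot decide on free RNA in library 1. A copy number that differs between the tumours is a candidate explanation, since the medians of the lower and upper part of each arm correlated at 0.855 across arms. Any cause that shifts whole arms would give such a correlation, so it does not single out copy number. Within library 2 alone, arm medians of cluster 7 over the other clusters had an SD of 0.329, above the 0.203 between the libraries. Whether a difference in copy number, if there is one, arose before injection, in the mouse or with the knockdown stays open, with 1 tumour per group.

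Cluster 5 of library 2 had low MYC and OTX2, with MYC from 58.0 to 390 CPM over its subclusters. Photoreceptor, neuronal and muscle genes were each high in a different subcluster, and no list of muscle genes was scored. In the smallest joint cluster the photoreceptor list was at 0.21, within its random lists (percentile 57.2). Whether cluster 5 holds differentiated tumour cells was not tested. Mouse cells are argued against, since the share of UMIs on human lnc- features in cluster 5 was 138% of that in the other cells. That share also depends on the rest of the RNA, where ribosomal proteins were lower. Of human genes chosen after their values were seen, MAGEA1 measured 92.8 against 108 CPM and PAGE1 529 against 1004 CPM. Doublets with a typical tumour cell are argued against, since the median depth of cluster 5 was 38.0% (bootstrap interval 34.9 to 40.3) of that of the other cells. Fewer copies of the MYC region are a candidate explanation, since 4 other genes within 2 Mb of MYC (PCAT1, CASC11, PVT1 and LINC00824) had a median log2 ratio of -2.10 while the other 152 genes of 8q were at -0.03. Lower transcription stays open, because OTX2, on chromosome 14, was lower by as much (-2.09 against -2.16 for MYC). Library 2 was also clustered without the list genes, the fixed set of named genes and the MYC region. Then 208 of the 229 barcodes of cluster 5 again shared a cluster of 218, with MYC at 239.9 against 827 CPM. The leading genes of cluster 5 were not left out as a group, so that cluster may still rest on them.

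In cluster 7 of library 2 the ribosomal protein list was at -1.66, oxidative phosphorylation at -0.71 and the mitochondrial genome at 0.98 on the log2 scale against the other clusters, at a median depth of 8784 UMIs. MYC measured 1176 against 781 CPM while arm medians were above 0 on all arms but 19p, 17p and 19q, from -0.69 on 19q to 0.98 on 18p with 0.73 on 8q, and the MYC target list was within its random lists (percentile 31.8). TOP2A measured 292 against 133 CPM.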
